A study of Mus musculus with 6 samples.

How the data were processed

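RNA-seq libraries from 6 samples of CAD cells were compared, 3 with siRNA against circGigyf2 (siCircGigyf2) and 3 with control siRNA (siNC). Group and replicate number came from the sample titles and treatment labels, and each column of the table was matched to a sample by its title. Per the labels' protocols, total RNA was depleted of ribosomal RNA with a removal kit, made into libraries and sequenced as paired reads. Nothing in the labels says that the replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

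The authors deposited 1 table of FPKM, fragments per kilobase of transcript scaled to each library's mapped fragments, with 1 row per gene symbol and 1 column per library. Per the submitters' processing notes the genome build was mm9. The aligner, the quantifier, the annotation and any further scaling were not given in the sources used here, and neither was strand handling, so overlapping antisense genes cannot be separated. FPKM are not counts, and no count model was used. Absolute depth was not given. Low FPKM values came in steps of a single fragment, and the ratio of these steps over genes with FPKM under 0.3 gave each library's depth relative to siNC replicate 1. Exact zeros also occurred for RNAs that nearly all cells express, so a 0 is reported as "listed at 0" and no fold is given against a group at 0. No pair of libraries shared more than 0.0088% of its values, so none was counted as a repeat of another. FPKM are relative to the other genes of a library and cannot show a change in total RNA per cell.

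Genes with a mean FPKM of at least 1 over the 6 libraries were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (linear model of the 2 groups, empirical Bayes with a mean-variance trend, two-sided, no covariates). Adjusted p-values are Benjamini-Hochberg over all genes tested, with a threshold of 0.05. Differences are siCircGigyf2 minus siNC on the log2(FPKM + 1) scale, which understates the change of genes of low FPKM. A count of genes that differed at least 1.5-fold used the same scale and includes Prnp.

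Gene lists, 32 in number, were written before the data were examined. They cover the cell cycle, metabolism, protein folding, RNA metabolism, stress responses, neuronal and catecholaminergic identity, Alzheimer disease, the GIGYF2-4EHP complex and markers of other cell types. The 27 lists with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation passed 0 lists after adjustment (3 at an unadjusted p under 0.05), and fry, which asks whether a list's genes move on balance one way without comparing them with other genes, passed 23. Each list's counts are given over all genes tested and adjusted over the list alone.

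The rule for named genes was also fixed before the data were examined. It takes Gigyf2 and Aqr, the 10 largest rises and 10 largest falls among genes past the threshold whose groups did not overlap, for the 8 lists with the smallest camera p the 3 members with the smallest p, for any list discussed up to 4 members past the threshold, and the qPCR references Actb and Gapdh. Members named outside it are marked as named after their values were seen. Some members that the rule selects are not reported here; the counts and tests of their lists include them.

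Alternatives were a pseudocount of 0.1, no filter or a filter of 5 FPKM, median-of-ratios and quantile scaling, the replicate number as a block, no variance trend, robust empirical Bayes, both other list tests and leaving out each library in turn. Fits without genes listed at 0 in any library, and without genes holding a sequence motif in the 3' UTR, were added after seeing the data.

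Transcript sequences came from the GENCODE M21 annotation, which is on build GRCm38 and not on mm9. They were joined by gene symbol, taking the longest coding transcript of a gene, and served only for length, GC content, 3' UTR and coding sequence, and Gigyf2 exons. All 7-mers present in the 3' UTR of at least 50 of 10468 genes were tested for a relation to the log2 difference, with 3' UTR length, GC content and expression as covariates and 100 permutations of the differences over genes. This step used Python 3.11.15, numpy 2.4.6 and pandas 2.3.3.

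The gene test was tested on simulated data for this comparison, with 200 changed genes among 11420. It recovered 44.8% of genes changed 1.2-fold, 82.1% at 1.5-fold and 95.5% at 2-fold, and 10 of its 158 calls were false. The list test called 10 of 10 simulated lists shifted by 0.3 on the log2 scale and 0 of 90 unshifted lists. Genes were simulated independently of each other, so this does not show how the list test behaves where members are correlated.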

Results

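The data were gene-level RNA-seq values from CAD cells, a mouse catecholaminergic neuronal line. Cells had received either an siRNA against circGigyf2, a circular RNA formed by back-splicing of Gigyf2 exons, or a control siRNA. Each group held 3 libraries of total RNA depleted of ribosomal RNA, labelled siCircGigyf2 and siNC here. The table gave FPKM for 24318 genes, of which 7188 were listed at 0 in all 6 libraries. FPKM summed to between 604881 and 624645 in the siCircGigyf2 libraries and to between 578627 and 601552 in the siNC libraries. The number of sequenced fragments was not given, but the smallest steps between low values placed the depth of the siCircGigyf2 libraries at 0.839, 0.914 and 0.802 of that of siNC replicate 1, and the other siNC libraries at 0.980 and 0.953. The first principal component of the 11420 genes with a mean FPKM of at least 1 carried 61.0% of the variance and separated the groups. The median absolute log2 difference between libraries was 0.0572 to 0.0718 within groups and 0.135 to 0.145 between them.

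The comparison asks which RNAs differ once circGigyf2 has been targeted, in a series concerned with circular RNAs in Alzheimer disease. Gigyf2, the host gene, encodes a protein that works with the cap-binding protein 4EHP in translational repression. It averaged 21.4 ± 0.330 FPKM (SD, n = 3) with the circGigyf2 siRNA and 23.2 ± 0.0749 FPKM with the control siRNA, and fell by 0.11 on the log2(FPKM + 1) scale (SE 0.033, limma adjusted p = 0.0287). This gene-level value pools linear and circular molecules, and circGigyf2 itself has no row of its own. The fall was also smaller than the median absolute log2 difference of all changed genes (0.25), of which 2135 were lower. It is therefore a weak check of the knockdown label. The call was lost when any library but siCircGigyf2 replicate 1 was left out, with adjusted p from 0.0659 to 0.0845, and with the replicate number as a block (0.0598). Aqr, an RNA helicase of the spliceosome, averaged 27.4 ± 0.839 and 27.9 ± 1.18 FPKM, a log2 difference of -0.02 (SE 0.041, adjusted p = 0.681) that did not pass the test and changed sign, to 0.0028, without siNC replicate 2. Both reference genes of the submitters' qPCR protocol passed the test. Gapdh, a glycolytic enzyme, averaged 5049 ± 244 against 3969 ± 103 FPKM and rose by 0.35 (adjusted p = 0.00111), or 0.21 after quantile normalization. Actb rose by 0.12 (adjusted p = 0.0331), a call that was lost after quantile normalization with a log2 difference of 0.053 (adjusted p = 0.0839), without a filter on low values (0.104), and with any library but siCircGigyf2 replicate 2 left out (adjusted p from 0.0581 to 0.120).

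Expression differed over much of the transcriptome, by small amounts. Of 11420 genes tested, 4367 (38.2%) passed a limma adjusted p of 0.05, with 2232 higher and 2135 lower in the siCircGigyf2 libraries. Their median absolute log2 difference was 0.25. The same test gave 160 genes that differed at least 1.5-fold, 85 higher and 75 lower, and 12 that differed at least 2-fold, 9 higher and 3 lower. With a pseudocount of 0.1 in place of 1, 317 genes differed at least 1.5-fold, 147 higher and 170 lower. The libraries of the groups did not overlap for 5822 genes (51.0%), where chance gives 10% for 3 against 3. The median log2 difference over all tested genes was 0.00035.

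**Figure D1:**
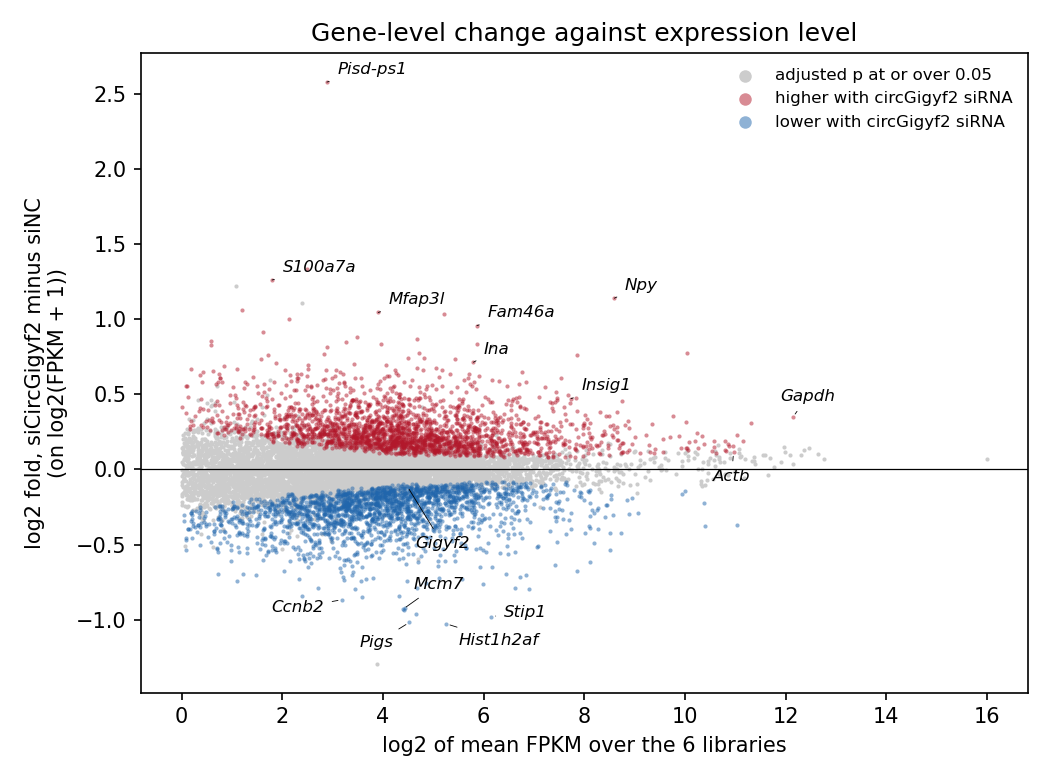
Log2 difference between the siCircGigyf2 and siNC groups on log2(FPKM + 1) (vertical) against the log2 of the mean FPKM (horizontal), with 1 point per tested gene that had a value above 0 in all 6 libraries. Points in red (higher) and blue (lower) passed a limma adjusted p of 0.05, and most of them lie within a 1.5-fold difference.

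The rises of largest size included a neuropeptide gene at high abundance. Npy, which encodes neuropeptide Y, averaged 533 ± 32.7 FPKM (SD, n = 3) against 241 ± 9.04 FPKM, a ratio of 2.21 and a log2 rise of 1.14 (SE 0.048, limma adjusted p = 3.91e-06). Fam46a, of a family of noncanonical poly(A) polymerases, averaged 77.4 ± 1.13 against 39.4 ± 1.21 FPKM, and Mfap3l 20.5 ± 0.979 against 9.44 ± 0.201 FPKM. Genes of lower abundance rose as well. S100a7a, of the S100 calcium-binding family, averaged 5.32 ± 0.701 against 1.63 ± 0.192 FPKM, Acap1, an Arf GTPase-activating protein, 3.47 ± 0.201 against 1.15 ± 0.130, 1700124L16Rik 6.18 ± 1.06 against 2.58 ± 0.448, and Cox6b2, a cytochrome c oxidase subunit, 4.30 ± 0.736 against 1.85 ± 0.604. Adjusted p for these 6 genes lay between 2.02e-06 and 0.00231. Pisd-ps1 (12.8 ± 10.6 against 1.98 ± 3.38 FPKM) and Rnaset2a (8.43 ± 2.73 against 2.83 ± 1.46 FPKM) also rose (adjusted p = 0.0222 and 0.00803), but both share sequence with near-identical copies. The call for Pisd-ps1 was lost without siCircGigyf2 replicate 1 (adjusted p = 0.0793), siNC replicate 1 (0.0702) or siNC replicate 3 (0.071), without a filter on low values (0.0801) and with robust empirical Bayes (0.134), and its log2 rise of 2.58 was 4.52 with a pseudocount of 0.1. Prnp, the prion protein gene, was listed at 1409, 1420 and 1413 FPKM in the siCircGigyf2 libraries and at 0 in all 3 siNC libraries. Malat1, an abundant nuclear RNA, was listed at 0 in all 6 libraries, so a 0 in this table need not mean absence. Rn45s, the ribosomal RNA precursor, was also listed at 0 in all 6, but the libraries were depleted of ribosomal RNA.

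The falls of largest size were about 2-fold. Pigs, a subunit of the GPI transamidase, averaged 14.9 ± 0.627 FPKM (SD, n = 3) against 31.2 ± 1.09 FPKM and fell by 1.02 on the log2 scale (SE 0.043, limma adjusted p = 3.91e-06). Stip1, a co-chaperone that links Hsp70 and Hsp90, averaged 47.7 ± 3.55 against 94.8 ± 0.581 FPKM, a ratio of 0.503. Ass1, argininosuccinate synthase, averaged 14.4 ± 1.56 against 28.4 ± 1.87 FPKM, and Mrps24, a protein of the mitochondrial ribosome, 14.6 ± 1.72 against 28.5 ± 1.77 FPKM. The replicative helicase subunit Mcm7 averaged 14.1 ± 0.681 against 27.9 ± 2.57 FPKM, the mitotic cyclin gene Ccnb2 6.17 ± 0.215 against 12.1 ± 0.455, the S-phase enzyme gene Tk1 8.28 ± 1.59 against 15.5 ± 1.13, and the ciliary gene Cc2d2a 3.49 ± 0.363 against 7.05 ± 0.635. Adjusted p for these 7 genes lay between 7.86e-06 and 0.000511. The histone genes Hist1h2af (24.8 ± 2.36 against 51.4 ± 1.17 FPKM, adjusted p = 1.59e-05) and Hist1h2bh (17.7 ± 7.91 against 33.1 ± 2.79 FPKM, adjusted p = 0.0214) belong to a family of near-identical copies, and Hist1h2bh did not pass without siNC replicate 2 (adjusted p = 0.0581) or siNC replicate 3 (0.0577), without a filter on low values (0.0778) or with robust empirical Bayes (0.124), and its log2 fall of 0.96 was 0.59 without siCircGigyf2 replicate 1. The annotated 3' UTRs of Pigs, Stip1, Ass1, Mrps24 and Ccnb2 held the 8 bases GCCTACAA, and that of Mcm7 held GCCTACA. Those of Tk1, Cc2d2a and Hist1h2bh held neither, and no 3' UTR was searched for Hist1h2af.

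**Figure D2:**
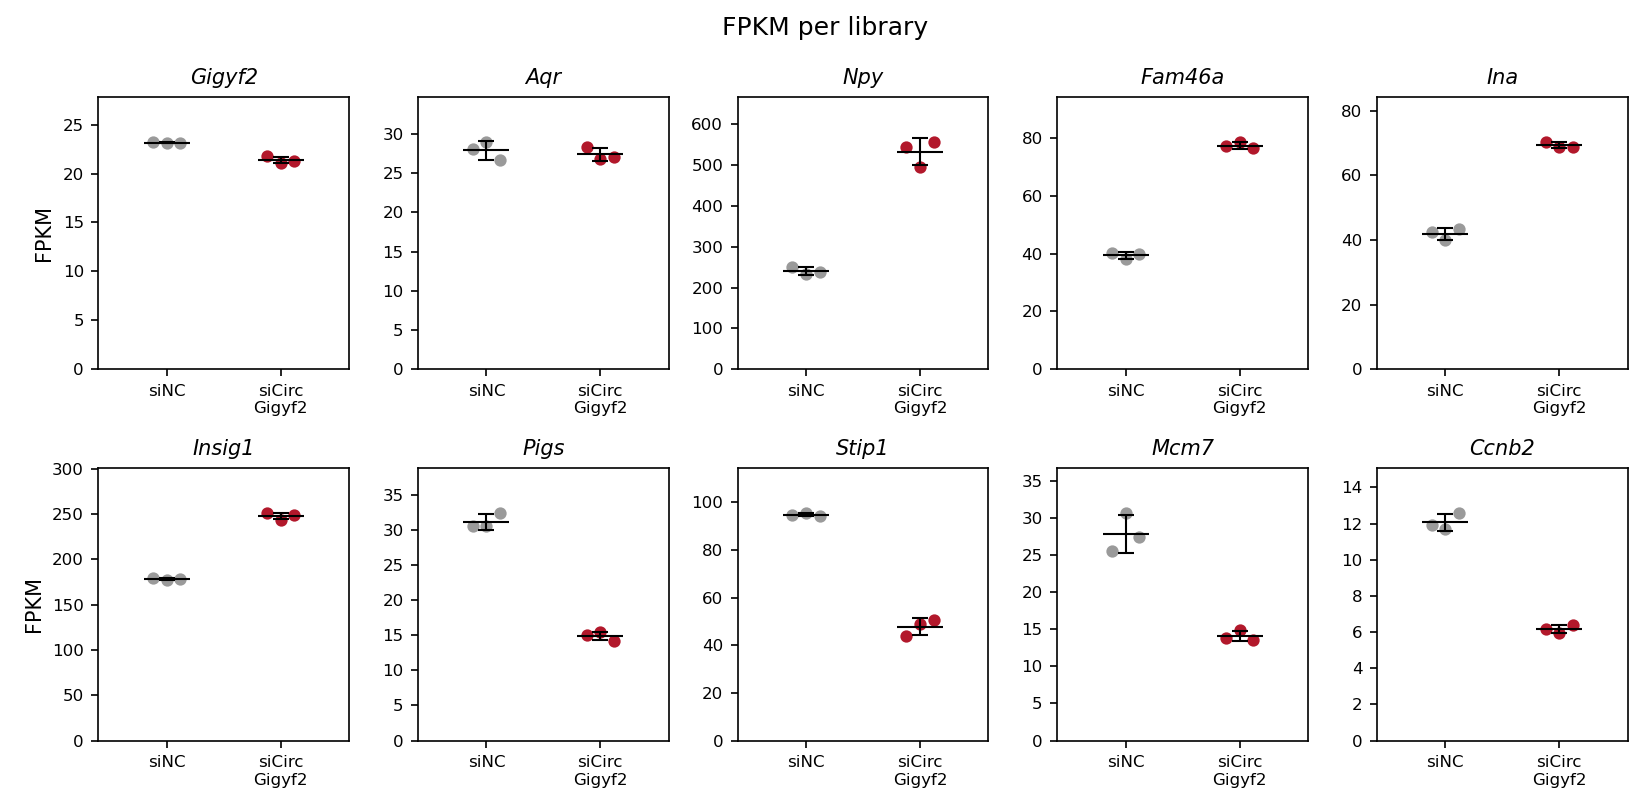
FPKM of 10 genes (vertical, linear from 0) in the 3 siNC libraries (grey) and the 3 siCircGigyf2 libraries (red), with 1 point per library and bars for the mean and SD. Gigyf2 lies within 21.1 to 23.2 FPKM in all libraries, whereas Npy, Fam46a, Pigs, Stip1, Mcm7 and Ccnb2 differ about 2-fold between groups whose libraries do not overlap.

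Genes of the cell division cycle were lower in the siCircGigyf2 libraries. Of 43 replication-dependent histone genes tested, 34 fell and 0 rose (35 and 0 adjusted over the list alone), with a median log2 difference of -0.40. Examples were Hist1h4b at 178 ± 4.15 against 286 ± 18.1 FPKM (SD, n = 3) and Hist1h1b at 79.7 ± 5.12 against 131 ± 9.22 FPKM. Of 36 genes of G2/M and mitosis, 31 fell and 2 rose (32 and 3 adjusted over the list alone; median -0.33), among them Ccnb2, the spindle motor Kif11 (8.64 ± 0.382 against 15.1 ± 0.416 FPKM), the cyclin gene Ccna2 (20.8 ± 0.756 against 29.9 ± 1.25) and the kinetochore gene Nuf2 (13.6 ± 0.270 against 18.8 ± 0.390). Of 38 genes of DNA replication and S phase, 26 fell and 1 rose (26 and 1 adjusted over the list alone; median -0.32). These included Mcm7, Mcm6 (9.93 ± 0.543 against 15.4 ± 0.484 FPKM), the histone mRNA-binding factor Slbp (34.6 ± 1.74 against 47.8 ± 1.24) and the polymerase clamp Pcna (71.3 ± 2.42 against 90.9 ± 0.493). The members that rose were Cdc25b, Cks2 and E2f1, named after their values were seen. Camera, which compares a list with all other genes, gave adjusted p = 5.85e-12, 1.60e-10 and 2.10e-08 for these lists in turn. The calls were lost when the correlation between members was estimated from these libraries, at adjusted p = 0.328, 0.389 and 0.328 with an estimated correlation. The 3' UTR of Kif11 held GCCTACA, which 4 of 73 replication and mitosis genes searched carried (5.48%, against 7.30% of all genes searched). Those 4 genes had a median log2 difference of -0.80, against -0.32 for the members without it, but the sequence was picked from these same differences.

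Genes of glucose and sterol metabolism and of protein folding in the endoplasmic reticulum were higher. Of 30 glycolysis and hypoxia-responsive genes, 21 rose and 0 fell (23 and 0 adjusted over the list alone; median 0.21, camera adjusted p = 4.64e-07; adjusted p = 0.455 with an estimated correlation). Ndrg1 averaged 7.06 ± 0.553 against 4.25 ± 0.181 FPKM (SD, n = 3), the glucose transporter gene Slc2a1 117 ± 7.89 against 83.9 ± 6.46, the mitophagy receptor gene Bnip3 452 ± 30.0 against 346 ± 11.5, and the oxygen sensor gene Egln1 80.3 ± 2.48 against 66.1 ± 1.80. Of 23 genes of cholesterol synthesis and uptake, 16 rose and 1 fell (16 and 2 adjusted over the list alone; median 0.31, camera adjusted p = 2.53e-06; adjusted p = 0.389 with an estimated correlation). Insig1, a sterol-regulated retention factor, averaged 248 ± 3.67 against 178 ± 0.795 FPKM, and the synthesis enzymes Cyp51, Lss and Sqle rose by 0.39, 0.41 and 0.37 on the log2 scale. Stard4, a sterol carrier, was the member that fell (-0.15), named after its value was seen. Of 24 endoplasmic reticulum chaperone genes, 14 rose and 2 fell, in both adjustments, over all genes and adjusted over the list alone (median 0.14, camera adjusted p = 0.00775; adjusted p = 0.470 with an estimated correlation). Pdia6, a disulfide isomerase, averaged 239 ± 2.41 against 169 ± 7.38 FPKM and Pdia4 79.4 ± 0.927 against 66.9 ± 0.908 FPKM. Sec61b and Dnajc3 fell, by 0.20 and 0.16, and were named after their values were seen. Of 42 lysosome and autophagy genes, 20 rose and 7 fell (21 and 7 adjusted over the list alone; median 0.10). Ctsl and Ctsz rose by 0.26 and 0.27, whereas Gusb, beta-glucuronidase, fell by 0.38. The list lay close to the threshold (camera adjusted p = 0.0495; adjusted p = 0.562 with an estimated correlation) and was lost without siCircGigyf2 replicate 1, 2 or 3 (adjusted p = 0.0752, 0.0677 and 0.0675), without siNC replicate 2 (0.0847), after quantile normalization (0.176, median 0.061), with a pseudocount of 0.1 (0.0507), with a filter of 5 FPKM (0.0927) and with the replicate number as a block (0.0602).

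Genes of the neuronal cytoskeleton and synapse were also higher. Of 26 tested, 13 rose and 3 fell (13 and 4 adjusted over the list alone; median 0.15, or 0.088 without a filter on low values, camera adjusted p = 0.00815; adjusted p = 0.328 with an estimated correlation). The intermediate filament gene Ina averaged 69.3 ± 0.919 against 41.9 ± 1.77 FPKM (SD, n = 3), the growth cone gene Gap43 94.9 ± 3.20 against 62.7 ± 1.98, the neuronal tubulin gene Tubb3 177 ± 8.53 against 120.5 ± 4.05, and the RNA-binding protein gene Elavl3 17.2 ± 0.173 against 12.4 ± 0.246. Rab3a, Mapt and Nefh fell by 0.21, 0.15 and 0.18, and were named after their values were seen. Of 28 immediate early genes, 15 rose and 1 fell (16 and 1 adjusted over the list alone; median 0.23, camera adjusted p = 9.83e-05; adjusted p = 0.328 with an estimated correlation). Btg2, an antiproliferative gene, averaged 23.5 ± 1.13 against 14.5 ± 0.400 FPKM even though its 3' UTR held GCCTACAA, and Klf6, Maff and Jun rose by 0.46, 0.42 and 0.36. The phosphatase gene Dusp1 was the member that fell (-0.27), named after its value was seen. Btg2 was not the only named gene to rise with the site. In other lists Ago4 rose with GCCTACAA in its 3' UTR, and Bace2 and Egln1 rose with GCCTACA, whereas Tnrc6c and Mbnl1 fell with GCCTACA. Of 19 extracellular matrix genes, 10 rose and 1 fell (11 and 1 adjusted over the list alone; median 0.13, or 0.050 without a filter on low values, camera adjusted p = 0.00567; adjusted p = 0.389 with an estimated correlation). Nid1, Sparc and Timp2 rose by 0.55, 0.33 and 0.32, and Loxl2, a lysyl oxidase with GCCTACAA in its 3' UTR, fell by 0.54. Of 15 interferon-stimulated genes, 7 rose and 0 fell, and the same counts held adjusted over the list alone (median 0.27, camera adjusted p = 0.00924; adjusted p = 0.328 with an estimated correlation). Parp14, Mx2, Eif2ak2 and Lgals3bp rose by 0.56, 0.43, 0.29 and 0.30, with Parp14 at 1.02 for a pseudocount of 0.1. The list did not pass without siCircGigyf2 replicate 2 (median 0.172, adjusted p = 0.0664), without a filter on low values (median 0.047, adjusted p = 0.0569) or with a filter of 5 FPKM (median 0.024, adjusted p = 0.477).

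**Figure D3:**
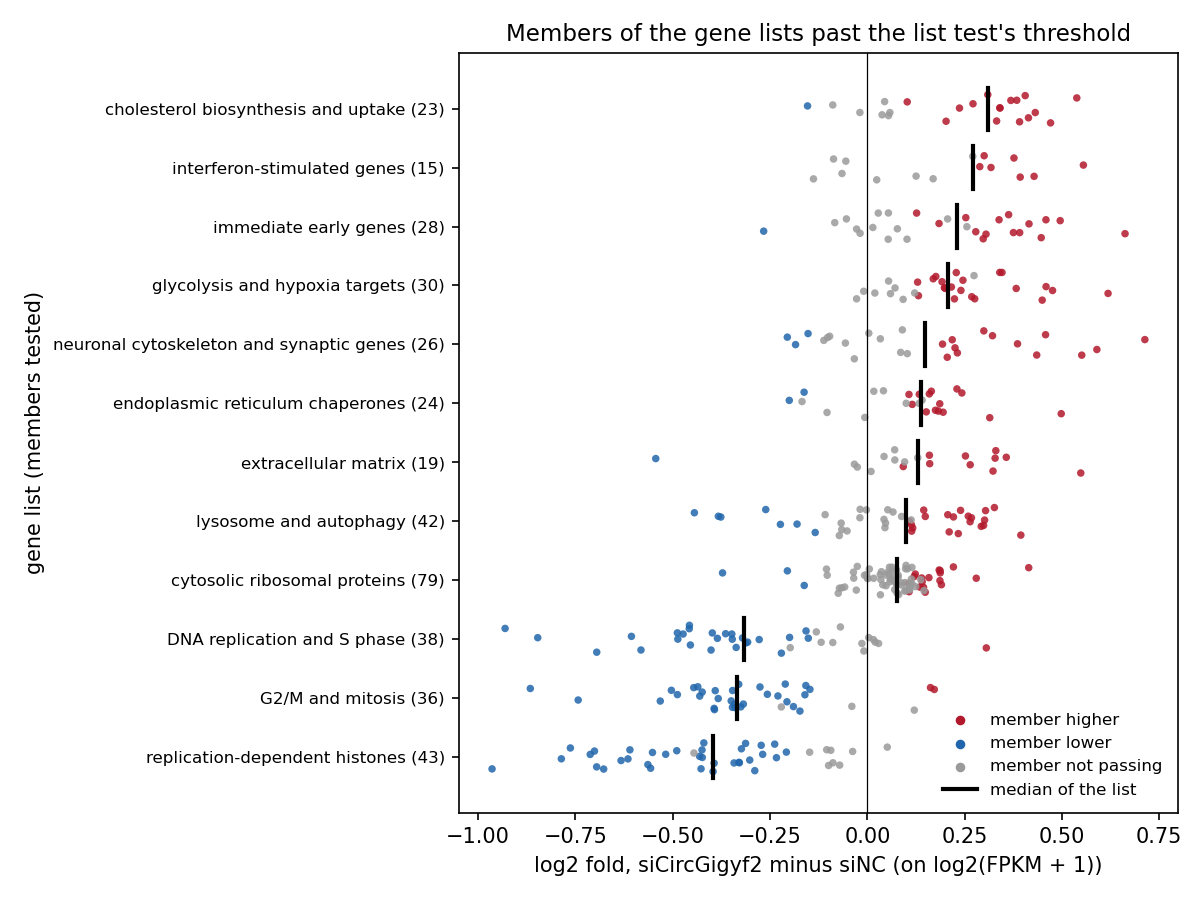
Log2 difference between the siCircGigyf2 and siNC groups on log2(FPKM + 1) (horizontal) for each tested member of the 12 gene lists past the camera threshold (vertical, number of members in brackets). Red and blue members passed a limma adjusted p of 0.05, grey members did not, and the black bar is the list's median, which runs from -0.40 for histone genes to 0.31 for cholesterol genes and changed sign for ribosomal proteins after quantile normalization (-0.0033).

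Cytosolic ribosomal protein genes differed by little. Of 79 tested, 18 rose and 3 fell (15 and 3 adjusted over the list alone; median 0.08, camera adjusted p = 0.00235; adjusted p = 0.562 with an estimated correlation), but after quantile normalization the median was -0.0033 and the list did not pass (adjusted p = 0.605). Rps27 and Rpl29 rose by 0.41 and 0.28. Rps3 and Rpl37a were among the members that fell, named after their values were seen. Processed pseudogenes of this family can share reads, so its values are uncertain.

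Lists drawn up for the Alzheimer setting and for the biology of circGigyf2 did not pass camera in the main comparison. Each held changed members in both directions, where 38.2% of all genes tested had changed. Of 28 Alzheimer disease genes, 11 rose and 6 fell (12 and 7 adjusted over the list alone; median 0.06, camera adjusted p = 0.289; adjusted p = 0.470 with an estimated correlation). Without genes that hold a 7-mer or 8-mer site of the GCCTACA type in the 3' UTR, a set picked from these same falls, the list passed (median 0.15, adjusted p = 0.0165). App, the amyloid precursor, averaged 197 ± 0.907 against 165 ± 2.11 FPKM (SD, n = 3), the secretase gene Bace2 121 ± 2.01 against 89.7 ± 1.22 and Clu 61.5 ± 0.435 against 51.3 ± 0.496, whereas Aplp2, an App paralog, averaged 93.0 ± 1.45 against 112.6 ± 2.26. Bace1, Adam10, Adam17, Mapt and Cd2ap, named after their values were seen, also fell. Of 17 catecholaminergic markers, 4 rose and 5 fell (5 and 7 adjusted over the list alone; median -0.09, camera adjusted p = 0.888). Gch1, Scg2, Hand2 and Slc18a1 rose by 0.47, 0.36, 0.18 and 0.33, and Gata2, Chgb, Phox2a, Chga and Dbh, named after their values were seen, fell. Of 12 genes of the GIGYF2-4EHP repression complex, 4 rose and 3 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.881), and the median (-0.016) and the mean (0.038) differed in sign. Tnrc6b and Gigyf1 rose by 0.58 and 0.20, and Cnot1 and Tnrc6c fell by 0.18 and 0.23. Of 13 genes of the microRNA pathway, 6 rose and 1 fell, with the same counts adjusted over the list alone (median 0.08, camera adjusted p = 0.110). The Argonaute genes Ago2, Ago3 and Ago4 and the let-7 regulator Lin28b rose, by 0.31, 0.45, 0.41 and 0.37, and Drosha, named after its value was seen, fell. Of 16 heat shock genes, mostly of cytosolic chaperones but with the mitochondrial chaperonins Hspd1 and Hspe1, 3 rose and 6 fell, with the same counts adjusted over the list alone (median -0.0010, camera adjusted p = 0.434). Hspd1, with GCCTACA in its 3' UTR, averaged 86.4 ± 3.07 against 151 ± 3.29 FPKM and Hsp90ab1 1180 ± 19.1 against 1533 ± 8.15 FPKM, while Hspa4l rose by 0.41.

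Further lists for RNA metabolism, stress and growth did not pass. For 34 core spliceosome and exon junction genes, 7 fell and 1 rose (6 and 0 adjusted over the list alone; camera adjusted p = 0.20), with Prpf6 and Sf3b3 down by 0.35 and 0.26 and Dhx15, named after its value was seen, up. For 17 transcripts sensitive to nonsense-mediated decay or hosting snoRNAs, 8 rose and 2 fell (9 and 2 adjusted over the list alone; adjusted p = 0.110), with Snhg5 and Snhg1 up by 0.26 and 0.30, Srsf3 down by 0.35, and Srsf7, named after its value was seen, also down. For 12 nonsense-mediated decay factors, 3 rose and 1 fell in both adjustments, over all genes and adjusted over the list alone (adjusted p = 0.434): Smg1, Upf3b and Upf1 rose, the Upf1 call being lost without siCircGigyf2 replicate 2 (adjusted p = 0.0649), siNC replicate 2 (0.0734) or siNC replicate 3 (0.0665). For 23 RNA-binding proteins linked to circular RNA, 2 rose and 5 fell (2 and 3 adjusted over the list alone; adjusted p = 0.507), and the median (0.0027) and the mean (-0.025) differed in sign. Celf1 and Hnrnpl rose, Nova2 and Mbnl1 fell, and so did Nova1, Dhx9 and Eif4a3, named after their values were seen. For 31 ribosome biogenesis genes, 3 rose and 10 fell in both adjustments, over all genes and adjusted over the list alone (adjusted p = 0.314), with Dkc1, Mybbp1a and Rrp1b down by 0.48, 0.27 and 0.36 and Ddx21 up by 0.25. For 71 nuclear-encoded genes of oxidative phosphorylation, 12 rose and 9 fell (9 and 7 adjusted over the list alone; adjusted p = 0.434), with Uqcrc2 and Ndufs6 down by 0.45 and 0.55 and Uqcrfs1 and Cox5a up by 0.21 and 0.22. For 24 axon guidance genes, 4 rose and 6 fell (5 and 7 adjusted over the list alone; adjusted p = 0.330), with Slit2 up by 0.31 and Nrp2 and Slit3 down by 0.45 and 0.37. For 19 p53 targets, 7 rose and 4 fell in both adjustments, over all genes and adjusted over the list alone (adjusted p = 0.507), with Btg2, Ccng1 and Trp53inp1 up and Apaf1 down. For 31 genes of the integrated stress response, 7 rose and 8 fell (7 and 9 adjusted over the list alone; adjusted p = 0.775), with Sesn2 up by 0.39 and Aldh18a1 and Atf5 down by 0.34 and 0.29. For 8 NF-kB and inflammatory targets, Nfkbie rose and Csf1 fell, in both adjustments, over all genes and adjusted over the list alone (adjusted p = 0.314), and the Csf1 call was lost without siCircGigyf2 replicate 2 (adjusted p = 0.068), siNC replicate 2 (0.0511) or siNC replicate 3 (0.0824) and without a filter on low values (0.0528).

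Markers of other cell types were mostly under the level tested. Of 12 astrocyte markers 4 were tested, of which Fgfr3 and Glul rose and Sox9 fell. Of 15 microglia and macrophage markers 2 were tested and fell, Tmem119 among them. Of 12 oligodendrocyte markers 2 were tested and 0 passed, and of 16 fibroblast and endothelial markers 3 were tested and Col1a1 rose. These genes were named after their values were seen, and the list test was not run on lists with fewer than 5 tested members. Mitochondrially encoded genes had no rows in the table used here.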

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

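The fits without genes listed at 0 and without genes that hold the 3' UTR motif were chosen after seeing the data, and the other alternatives before. The number of changed genes stayed within 1.5 times of 4367 in each alternative, from 3521 (without siNC replicate 1) to 4423 (median-of-ratios scaling), and 94.46% of the called genes were called in the same direction after quantile normalization, which moved the log2 differences by a median of 0.0148 (95th percentile 0.0333). These shifts were small beside the median absolute log2 difference of 0.25 among changed genes, so most calls could hardly be lost. This test, chosen after the result was seen, argues only against a scaling difference that quantile normalization removes as the whole cause of the count. Median-of-ratios scaling moved the differences by a median of 0.0013 and so tests little. The count of genes that differed at least 1.5-fold rose from 160 to 317 (147 higher, 170 lower) with a pseudocount of 0.1, which shrinks genes of low FPKM less. Without genes that hold a 7-mer or 8-mer site, 44 genes in place of 75 were lower at least 1.5-fold, and 31 genes lower by that much hold such a site. The number of lists past the threshold went from 12 to 0 with an estimated correlation and to 23 with fry, and was 10 to 12 with a library left out. Apart from the estimated correlation, 9 of the 12 list calls were lost in 0 of the settings run, and the exceptions were the lysosome, interferon and ribosomal protein lists. The ribosomal protein list had a median of -0.0033 under quantile normalization, and fry gave the catecholaminergic list (median -0.0946) the opposite direction to camera. For both, the cause was not tested. The Alzheimer disease list passed (median 0.15, adjusted p = 0.0165) without genes that hold the motif, which was picked from these same falls, and did not pass with an estimated correlation over all genes (adjusted p = 0.470).

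The host gene Gigyf2 kept its direction in all 16 alternatives, with adjusted p from 0.0207 to 0.0845. It passed in 10 of them. Its log2 difference was -0.121 to -0.10 with a library left out. With the replicate number as a block (replicate block) it was -0.109 (adjusted p = 0.0598). Aqr, which passed in none of these fits, ranged from -0.0557 to 0.0028 with a library left out. The cause of these shifts was not tested. Under the replicate block 3973 genes passed, 3856 of them called in the main comparison in the same direction. The replicate numbers are shared between groups by the titles only. Deviations from the group means correlated at 0.163, -0.0208 and 0.0025 across genes for libraries with the same number, and not every library correlated best with its own number, so the numbers are not read as pairs. The absolute depth is unknown, which leaves the counting error of single values unknown. The simulated recovery of 44.8% at 1.2-fold came from a simulation with 158 calls, against 4367 in the real comparison. The adjusted threshold depends on the share of changed genes, so this recovery does not show what share of small differences was missed here.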

Other observations

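The tests of gene families by symbol, other splits of the samples, genes matched by FPKM or by length and GC content, Prnp, seed-site types, the number of large falls with a site and the counts without genes that hold the motif were chosen after results were seen. Of 177 families of genes that share a symbol stem, camera passed 2, both lower. The Hist family had 41 of 56 members lower and 0 higher (median -0.40, adjusted p = 2.68e-12), and the Mcm family, which holds the subunits of the replicative helicase, 8 of 10 lower and 0 higher (median -0.47, adjusted p = 0.00223). Neither passed with an estimated correlation (adjusted p = 0.868 for both). Families that did not pass included Parp, ADP-ribosyltransferases with 7 of 11 members higher and 0 lower (adjusted p = 0.198), and Ift, the intraflagellar transport genes of cilia, with 6 of 14 lower and 0 higher (adjusted p = 0.245).

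Genes that held a particular 7-base sequence in the 3' UTR were lower at the median in the siCircGigyf2 libraries, though some rose. GCCTACA occurred in the 3' UTRs of 764 of 10468 genes searched and went with a log2 difference of -0.13. Its z was the most negative of 16077 7-mers, and 0 of 100 permutations gave a z as extreme for any 7-mer. CCTACAA, AGCCTAC and TGCCTAC, which overlap it, came next. The median log2 difference was -0.126 for 166 genes with the 8-mer GCCTACAA, -0.087 for 598 genes with GCCTACA as the best site, -0.036 for 509 genes with CCTACAA, -0.0062 for 1443 genes with CCTACA alone and 0.010 for 7752 genes with none of these. Among the 166 genes 76 were called lower and 22 higher, and among the 598 genes 213 lower and 81 higher. Of the 7752 genes, 1293 were called lower and 1604 higher. Of 67 searched genes that fell at least 1.5-fold, 31 held a 7-mer or 8-mer site, a count that is no separate evidence, since the site was picked from these same differences. Besides the genes named in the comparison, large falls with a site included Hadh, a mitochondrial fatty acid oxidation enzyme (14.1 ± 0.976 against 26.0 ± 0.392 FPKM, SD, n = 3), Gng10, a G protein subunit, Ykt6, a SNARE protein, Gspt1, a translation release factor, and F2r, the thrombin receptor (56.0 ± 0.331 against 88.4 ± 3.00 FPKM). In the other direction AAGACAA had the most positive relation (z of 6.33, against a 95th percentile of 4.53 of the permuted maxima), and the medians were 0.056 for 339 genes with TAAGACAA, 0.022 for 869 with TAAGACA as the best site, 0.020 for 1055 with AAGACAA, -0.0040 for 2074 with AAGACA alone and -0.0088 for 6131 with none of these. The order of medians by site type does not decide on seed pairing, since the first site was picked from these differences. The second motif, which goes with higher expression, shows the mirrored order. That order does not decide either, because the other group received a control siRNA whose sequence is not given in the sources used here.

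The relation to GCCTACA may reflect repression by seed pairing of a small RNA. Its z of -16.37 lay beyond the 5th percentile of the permuted minima (-4.47), as predicted for such repression. The permutations test only for no relation between the differences and 3' UTR sequence. They cannot tell seed pairing from another cause tied to sequence. The other 419 7-mers made of the same bases had a median z of -0.1179 (SD 1.28). GC content was already a covariate, so these values argue against base composition only beyond GC content. In coding sequence the 7-mer went with -0.075 (SE 0.0061), 0.5897 of its effect in the 3' UTR (-0.127, SE 0.0079). These effects came from a separate fit with only the lengths of the 3' UTR and coding sequence as covariates, not GC content or expression. The ratio leaves a trend of whole transcripts in part open. The siRNA sequence is not given in the sources used here, but the reverse complement TGTAGGC lies across 2 of 378 possible back-splice junctions of Gigyf2 and in 0 places within its exons: exon 8 of 29 joined to exon 4 (ATGTAGGCTCCG) or to exon 7 (ATGTAGGCAGAG), on chromosome 1 of GRCm38, with exon 8 ending at 87380008 and exons 4 and 7 starting at 87364104 and 87378972. That would fit the sense strand of a junction-spanning siRNA acting as a guide, although 9.92% of all 7-mers lie across at least 1 such junction and 45.3% lie in an exon or junction on either strand, and a microRNA remains open because none was measured here. Of 2009 searched genes called lower, 1293 (64.36%) lacked even the 6-base core of the site in the 3' UTR. So did 7752 of all 10468 genes searched, a larger share. Sites in coding sequence were not counted here. The site in the 3' UTR leaves most falls open, and how far they follow from loss of circGigyf2 was not tested.

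The fall of histone, replication and mitosis genes was weighed against scaling, transcript properties and the same site. Its members had a median log2 difference of -0.339 (SD 0.237), and lay a median of -0.3653 (SD 0.248) from 20 genes outside the lists matched to each by mean FPKM, a difference in which a factor common to a library's genes of like FPKM cancels. Genes matched by length and GC content had a median of -0.005078 (SD over members 0.0505), so these values argue against library scaling and against length or GC content as the whole cause of the difference from other genes. Replication and mitosis genes without GCCTACA had a median of -0.3208 (SD 0.206), which argues against the site within these genes as the whole cause. Indirect effects of other genes with the site, a change in the share of dividing cells and an effect of circGigyf2 loss remain open and were not tested.

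Prnp was listed at 0 in all 3 siNC libraries and near 1414 FPKM in the siCircGigyf2 libraries. A limit of the quantifier on abundant loci could give such zeros, and Malat1, listed at 0 in all 6 libraries, goes with one. Rn45s was also listed at 0 in all 6, but the libraries were depleted of ribosomal RNA. Genes were ranked by the product of mean FPKM in the siCircGigyf2 libraries and transcript length. Above Prnp, 28 genes had values in all 6 libraries and 0 were listed at 0 in any library. This does not exclude a limit, since a gene at 0 in the siCircGigyf2 libraries too, such as Malat1, cannot enter the ranking. The largest log2 difference among genes without an exact 0 was 2.577 (Pisd-ps1), which leaves the question open. A limit of this kind, another failed estimate and a true difference in Prnp RNA cannot be told apart, because the table holds no reads for the locus.

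For the count of changed genes, 1 of the 10 splits of the 6 libraries into 3 against 3, the real split with 4367 genes, gave as many, and the highest of the other splits gave 0 genes past the limma threshold. A total of 10 splits is too few for a share under 0.05.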
